A study of Homo sapiens with 9 samples.

How the data were processed

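The values analysed are gene-level FPKM as deposited by the authors, whose processing notes name fastp for read trimming, StringTie for the FPKM estimates and edgeR for their own differential tests, without versions. The aligner, genome build and annotation are not given in the sources used here, so no coordinates are used. Libraries were poly(A)-selected, dUTP-stranded and paired-end. Reads were not analysed here. FPKM is given to 2 decimals: in each library the smallest value above 0 is 0.01, held by 887 to 1253 genes, so sequencing depth cannot be recovered from the values.

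Of 41041 Ensembl identifiers, 41002 matched the name table and 29784 had a symbol. Genes with a mean FPKM of at least 1 over the 9 libraries were kept (12662, of which 11994 had a symbol), without regard to group. Values were taken as log2(FPKM + 1), which shrinks the fold changes of genes of low expression. No further scaling was applied.

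All 9 libraries entered one limma fit with a mean-variance trend (6 residual and 3.2 prior degrees of freedom), with 3 contrasts: SFN against control, SFN+5-FU against control and SFN+5-FU against SFN. P values are from limma's moderated statistics, adjusted over genes by the Benjamini-Hochberg method within each contrast. A gene is called, and said to rise or fall, at an adjusted p of 0.05. Each p value is two-sided. Each group mean rests on 3 libraries, and the spread is estimated over all 9 libraries together. A library that departs from its group therefore widens the SE in all 3 contrasts, also in the one that does not compare its group. The SE of a fold change comes from the moderated variance.

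Gene lists were fixed before the values were read. Of 29 lists, 26 had at least 5 tested genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 78 list tests. Camera was repeated with the correlation estimated from the data, and the lists were also tested with fry. The estimated correlation rests on 6 residual degrees of freedom. Members were also adjusted over their list alone, a smaller family.

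Genes are named by a fixed rule. Per contrast these are the 8 largest increases and 8 largest decreases among called genes with a symbol, a mean FPKM of at least 5 and no overlap between the groups, 2 called members of each list with the largest change, or the member of highest expression where none is called, and 27 genes chosen beforehand. Other genes (among them JMJD6, LEF1, C3, DHRS2 and IL11) were named after their values were seen. With 3 libraries in each group, 1 in 10 splits separates them completely by chance in either direction.

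Alternatives changed the filter, pseudocount, scaling, variance model, replicate block and libraries included. A correction of each library for GC content and transcript length (splines fitted to its difference from the gene means) used GENCODE release 29 for 12504 genes (98.8% of those tested). Spearman correlations of fold change with GC content were -0.192, -0.181 and -0.0952 and with length -0.151, -0.137 and -0.0575 in the 3 contrasts. Replicates with the same number were not treated as paired: of 9 same-number pairs, 1 had a correlation of deviations from the group means above 0.1 (range -0.143 to 0.107). Pairs with different numbers ranged from -0.247 to 0.182. Deviations in the SFN group hold the shift of SFN replicate 2 described below, so this check could miss a pairing.

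On simulated libraries of this size, changes of 0.5, 1 and 2 on the log2 scale were recovered for 46 of 66, 65 of 67 and 67 of 67 genes, with 12 false calls among 190. A list moved by -0.5 was called, with a median of -0.50. In all, 4 lists were called there, 3 of them sharing members with it. The simulated genes varied independently of each other, while the estimated correlation of the HIF-1 targets with SFN was 0.545. False list calls under such correlation were therefore not assessed.

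Work was done in R 4.3.3 with limma 3.58.1 and Biostrings 2.70.1, and in Python 3.11.15 with matplotlib 3.10.9.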

Results

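Poly(A) RNA was measured by sequencing in SW480 cells, an established human colorectal cancer line, after 48 h at 1% oxygen. The 9 libraries form 3 groups of 3 biological replicates. One group was untreated hypoxic cells (control), one received sulforaphane (SFN), an isothiocyanate from cruciferous vegetables, at 25 µM, and one received SFN with the pyrimidine analogue 5-fluorouracil (SFN+5-FU). The 5-FU dose and the SFN dose in the combined group are not given in the sources used here. They state 48 h both for the hypoxia and for the treatment, without saying whether the compounds were present throughout, so the exposure time behind each difference from control is not certain. These samples hold no normoxic group and no group on 5-FU alone. Expression is given as FPKM, a fragment count scaled by transcript length and library size. The FPKM values of a library summed to between 259184 and 272235, and the number of sequenced fragments behind them is unknown. Of 41041 genes, 12662 had a mean FPKM of at least 1 and were tested.

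The library labelled SFN replicate 2 lay with the SFN+5-FU libraries and not with the other SFN libraries. On log2(FPKM + 1) across the tested genes, its Pearson correlation was 0.993 with each SFN+5-FU library, 0.963 with SFN replicate 1 and 0.968 with SFN replicate 3, while SFN replicates 1 and 3 correlated at 0.990. Genes are not independent replicates, so these values describe similarity only. The library stays in its labelled group below, and values without it are given where it decides a call. Elsewhere it still enters each SFN mean, so a change given for SFN may differ from that in SFN replicates 1 and 3.

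**Figure D1:**
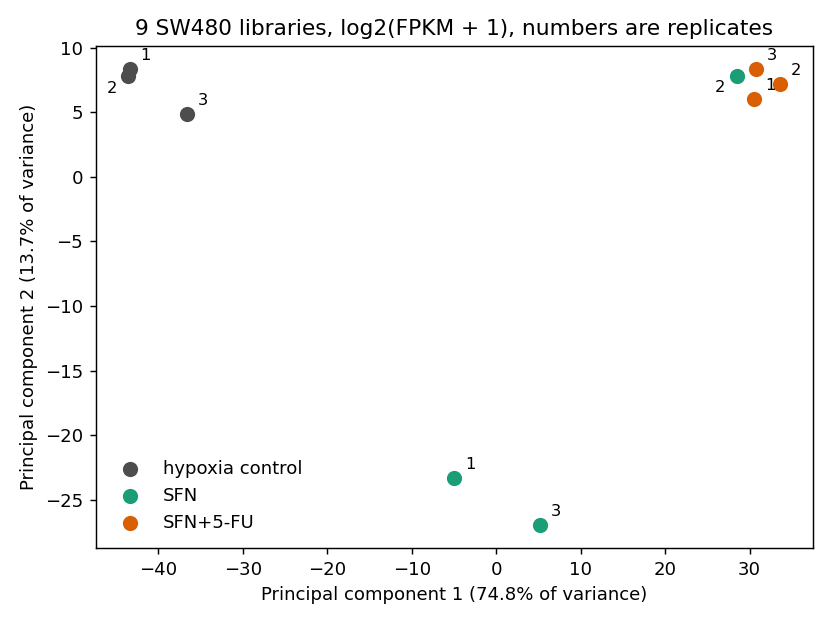
Principal components 1 (74.8% of variance) and 2 (13.7%) of log2(FPKM + 1) over the tested genes, with one point per library coloured by group and numbered by replicate. SFN replicate 2, at 28.5 on component 1, sits beside the SFN+5-FU libraries (30.5 to 33.6), while SFN replicates 1 and 3 lie at -5.00 and 5.19.

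The comparison of SFN with control asks what sulforaphane changes in hypoxic cells, and the series title names HIF-1α and the PI3K/AKT/mTOR pathway. Targets of HIF-1, the transcription factor of the hypoxia response, were lower with SFN. DDIT4, an inhibitor of mTOR complex 1, fell from 133 ± 18.9 to 30.9 ± 13.4 FPKM (mean ± SD, n = 3 in each group). SLC2A1, which encodes the glucose transporter GLUT1, fell from 487 ± 31.3 to 233 ± 61.9 FPKM. On the log2 scale DDIT4 and SLC2A1 fell by 2.16 and 1.09, and by 1.81 and 0.86 without SFN replicate 2. VEGFA, the angiogenic growth factor, fell from 5.20 ± 0.140 to 2.26 ± 0.0586 FPKM, and the aldolase gene ALDOC from 18.5 ± 1.83 to 3.69 ± 0.537 FPKM. HIF1A mRNA itself was 18.2 ± 1.23 FPKM in control and 19.5 ± 1.5 FPKM with SFN, a log2 fold change of 0.10 (adjusted p = 0.397, and 0.0377 with library weights, where it was 0.19).

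Over all tested genes 50.0% were called in this comparison, the background for the member counts that follow. Of the 42 tested HIF-1 targets, 29 fell and 1 (JMJD6) rose, with the same counts adjusted over the list alone. Their median log2 fold change was -0.60 (-0.689 to -0.435 without 1 library, camera adjusted p = 2.96e-09, and adjusted p = 0.548 with an estimated correlation). CA9, a carbonic anhydrase used as a hypoxia marker, fell by 0.73 on the log2 scale (adjusted p = 0.0183), a call lost without control replicate 1, without control replicate 2 and with no expression filter, where the adjusted p reached up to 0.0710 over a range from 0.00330. The lactate dehydrogenase gene LDHA was 438 ± 15.4 FPKM in control and 351 ± 130 FPKM with SFN (adjusted p = 0.200, and a log2 fold change of -0.40 that was -0.04 without SFN replicate 2), and PDK1, a pyruvate dehydrogenase kinase, was 2.85 ± 0.355 and 1.89 ± 0.846 FPKM (adjusted p = 0.0769), past the threshold only without SFN replicate 3 (adjusted p = 0.0225, with a highest of 0.243 over the alternatives). Among 9 tested HIF regulators, 3 fell and none rose, also adjusted over the list alone, and the list was not called (median log2 fold change -0.16, and -0.26 without SFN replicate 3, adjusted p = 0.175). EGLN3, an oxygen-sensing prolyl hydroxylase, fell by 1.61 on the log2 scale, and by 1.14 without SFN replicate 2. EPAS1, which encodes HIF-2α, fell by 1.01, and by 0.61 without SFN replicate 2. The glycolysis list shares 12 genes with the HIF-1 targets, so their results are not independent in any of the comparisons. Of 19 glycolysis genes 9 fell and none rose, with the same counts adjusted over the list alone. Their median log2 fold change was -0.40 (adjusted p = 0.000639, and adjusted p = 0.636 with an estimated correlation), and it was -0.18 without SFN replicate 2. The glucose transporter gene SLC2A3 fell from 587 ± 35.3 to 233 ± 18.1 FPKM.

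Transcripts of the PI3K/AKT/mTOR pathway did not move together. Of 26 tested components 3 rose and 5 fell (3 and 4 adjusted over the list alone), with a median log2 fold change of 0.01 (-0.02 to 0.04 without 1 library), a mean of -0.02 and a camera adjusted p of 0.712. AKT1 fell from 26.2 ± 0.200 to 18.8 ± 0.725 FPKM, a log2 fold change of -0.46 with an SE of 0.0578 and adjusted p = 0.000285. After correction for GC content and transcript length the change was -0.12 (adjusted p = 0.0944, in a range from 2.98e-06 over the alternatives), so that call depends on this correction. PIK3CD fell by 0.60 on the log2 scale, and PIK3R1 and EIF4E, the cap-binding translation factor, rose by 0.39 and 0.49. PIK3CA, AKT2, MTOR, RPS6KB1 and EIF4EBP1 had log2 fold changes of 0.21, -0.13, 0.05, -0.02 and 0.03, none past the threshold. PIK3CA was past it without SFN replicate 1 (0.32, adjusted p = 0.0349) and at 0.08 without SFN replicate 2, and MTOR was past it with library weights and after the GC and length correction (adjusted p = 0.0361 and 0.0333). These are mRNA levels, and phosphorylation of the pathway was not measured.

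Targets of NRF2, the transcription factor that sulforaphane is known to activate, moved in both directions. Of 33 tested targets 12 rose and 8 fell (13 and 8 adjusted over the list alone), and the list was not called (median log2 fold change 0.11, and 0.20 without SFN replicate 1, adjusted p = 0.365). The thioredoxin reductase gene TXNRD1 rose from 25.1 ± 1.96 to 63.1 ± 15.7 FPKM, the quinone reductase gene NQO1 from 67.9 ± 3.01 to 112 ± 10.5 FPKM, and the ferritin light chain gene FTL from 1632 ± 15.4 to 3375 ± 602 FPKM. SRXN1, which encodes sulfiredoxin, rose by 0.56 on the log2 scale. HMOX1 and GCLM, with log2 fold changes of 0.09 and 0.56, did not pass the threshold (adjusted p = 0.616 and 0.0590), although GCLM did without SFN replicate 1, with quantile normalization and with library weights. Without SFN replicate 2 their log2 fold changes were -0.10 and 0.26 (adjusted p = 0.225 and 0.0625). The cystine transporter gene SLC7A11 was below the expression filter, at 0.42 to 1.02 FPKM in all 9 libraries.

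The largest coordinated increase was in ribosome biogenesis, where all 26 tested genes rose, also adjusted over the list alone. Their median log2 fold change was 0.92 (adjusted p = 2.95e-12, and adjusted p = 0.548 with an estimated correlation). NOP16 rose from 13.9 ± 0.864 to 32.9 ± 0.251 FPKM and RRS1 from 12.7 ± 1.31 to 28.9 ± 1.62 FPKM. MYC, a transcription factor known to drive such genes, rose from 46.6 ± 2.40 to 93.8 ± 2.91 FPKM. Of 40 genes of G1/S and DNA replication 30 rose and none fell (32 and none adjusted over the list alone), with a median log2 fold change of 0.53 (adjusted p = 1.83e-07, and adjusted p = 0.548 with an estimated correlation). ORC6 and RFC3, which encode subunits of the origin recognition complex and of the clamp loader, rose by 1.13 and 1.11 on the log2 scale. Of 15 histone genes 11 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 fold change of 0.69 (adjusted p = 0.0129, and adjusted p = 0.548 with an estimated correlation). H4C8 and H2BC8 rose by 1.58 and 1.52, although reads of near-identical histone genes can be assigned wrongly and poly(A) selection captures these transcripts poorly. H2AZ1 is not a replication-dependent gene although the list holds it, and the list's call was lost after the GC and length correction and with a mean FPKM filter of 5 (highest adjusted p = 0.160). The G2/M and mitosis list was not called (median log2 fold change 0.18, adjusted p = 0.101), with 8 of 35 genes higher and none lower (7 and none adjusted over the list alone). Among these, UBE2C and CDK1 rose by 0.70 and 0.66, while MKI67, the proliferation marker Ki-67, was 21.4 ± 1.3 FPKM in control and 23.4 ± 3.04 FPKM with SFN (adjusted p = 0.324), past the threshold with library weights and after the GC and length correction (adjusted p = 0.00496 and 0.0228). Without SFN replicate 2, 19 of the 35 rose and the list was called (median 0.29, adjusted p = 0.000236, and adjusted p = 0.656 with an estimated correlation). It was also called without control replicate 3, with library weights and with no filter, and its median was 0.07 without SFN replicate 3.

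Cholesterol synthesis genes were lower with SFN: 20 of 24 fell and none rose (21 and none adjusted over the list alone), with a median log2 fold change of -0.87 (adjusted p = 1.72e-10, and adjusted p = 0.548 with an estimated correlation). INSIG1, the sterol-regulated retention factor of SREBP processing, fell from 31.1 ± 3.62 to 5.47 ± 0.604 FPKM. Of 19 Wnt targets 14 fell and 3 rose, with the same counts adjusted over the list alone and a median log2 fold change of -0.80 (adjusted p = 0.000988, and adjusted p = 0.548 with an estimated correlation). Their median difference from the control mean was -0.52, -1.20 and -0.60 in SFN replicates 1, 2 and 3, so replicate 2 enlarges this change. NOTUM, a secreted Wnt inhibitor, fell from 51.0 ± 4.32 to 10.3 ± 3.11 FPKM and the cyclin D1 gene CCND1 from 431 ± 8.07 to 255 ± 72.5 FPKM. The log2 fold change of CCND1 was -0.80, and -0.54 without SFN replicate 2. The 3 that rose were MYC, LEF1 and the Wnt antagonist gene DKK1, which rose from 2.16 ± 0.149 to 14.0 ± 4.37 FPKM. Of 27 ATF4 and integrated stress response genes 18 fell and 1 rose (19 and 2 adjusted over the list alone), with a median log2 fold change of -0.44 (adjusted p = 2.09e-05, and adjusted p = 0.548 with an estimated correlation). ASNS, which encodes asparagine synthetase, fell from 25.6 ± 3.06 to 6.58 ± 2.04 FPKM. DDIT3, which encodes CHOP, was 26.1 ± 1.41 and 25.3 ± 17.6 FPKM (adjusted p = 0.592), and without SFN replicate 2 it fell by 0.75 on the log2 scale (adjusted p = 0.000387).

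NF-kB inflammatory genes were higher: 9 of 16 rose and none fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.59 (adjusted p = 0.0141, and adjusted p = 0.548 with an estimated correlation). The apoptosis inhibitor gene BIRC3 and the adhesion molecule gene ICAM1 rose by 1.37 and 0.94 on the log2 scale. Of 18 heat shock genes 10 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 fold change of 0.45 (adjusted p = 0.0222, and adjusted p = 0.548 with an estimated correlation). The co-chaperone gene DNAJA1 rose by 0.80 and the small heat shock protein gene HSPB8 fell by 1.3, and the list's call was lost without SFN replicate 1, with quantile normalization and with library weights (highest adjusted p = 0.0945). Of 7 tested intestinal differentiation genes 4 fell and none rose (5 and none adjusted over the list alone), with a median log2 fold change of -0.28 (adjusted p = 0.0219, and adjusted p = 0.548 with an estimated correlation). CEACAM1 and the villin gene VIL1 fell by 0.79 and 0.78, and the list's call was lost with no expression filter (adjusted p = 0.186).

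The p53 target, apoptosis and 5-FU metabolism lists were not called in this comparison. Of 26 p53 targets 4 rose and 10 fell, also adjusted over the list alone (median log2 fold change -0.14, and -0.03 without SFN replicate 3, adjusted p = 0.336). BTG2 and GDF15 fell by 2.00 and 1.67, and CDKN1A, which encodes the cell cycle inhibitor p21, fell by 0.45 (adjusted p = 0.0164), a call lost without SFN replicate 3 (adjusted p = 0.0550, with a lowest of 3.38e-05 over the alternatives). Of 25 apoptosis regulators 10 rose and 2 fell, also adjusted over the list alone (median log2 fold change 0.17, and 0.04 without SFN replicate 2, adjusted p = 0.187). This list was called with no expression filter (adjusted p = 0.0227). The pro-apoptotic gene BMF fell by 1.49. Of 17 genes of 5-FU metabolism and transport 6 rose and 3 fell, also adjusted over the list alone (median log2 fold change 0.16, and 0.30 without SFN replicate 1, adjusted p = 0.395). This list shares 6 genes with that of G1/S and DNA replication, TYMS and RRM2 among them. TYMS, which encodes thymidylate synthase, the enzyme 5-FU blocks, rose from 41.3 ± 3.77 to 69.7 ± 20.8 FPKM, and the uridine phosphorylase gene UPP1 and the ribonucleotide reductase gene RRM2 rose by 1.38 and 0.90 on the log2 scale.

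In limma, 6333 of the 12662 genes passed an adjusted p of 0.05, 3478 higher and 2855 lower with SFN, and 593 of these changed at least 2-fold (195 higher and 398 lower). More were lower with median-of-ratios scaling (2977 higher and 3300 lower), with no filter (3303 and 3822) and with mitochondrial transcripts left out (3091 and 3188). Among called genes with a symbol and a mean FPKM of at least 5 whose groups did not overlap, the 8 largest increases were LINC00973, UBD, PI3, DKK1, KRTAP3-1, NRP1, IGHE and TOMM6, with log2 fold changes from 1.99 to 2.33. NRP1, the neuropilin-1 receptor gene, rose from 2.80 ± 0.0872 to 15.9 ± 0.789 FPKM. The 8 largest decreases were MYH7B, LINC02943, ENTPD8, PDGFA, INSIG1, NOTUM, CST1 and PRSS56, from -2.16 to -3.04, and the growth factor gene PDGFA fell from 74.0 ± 11.6 to 12 ± 1.89 FPKM. The increase of IGHE was 2.11, and 1.21 without SFN replicate 2, and its call was lost without control replicate 1 or control replicate 2. It was also lost with no filter, with a pseudocount of 5 and with only the 6 libraries compared (highest adjusted p = 0.0613). IGHE, KRTAP3-1 and TOMM6 lie in families of similar or overlapping sequence, so their identity is uncertain.

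**Figure D2:**
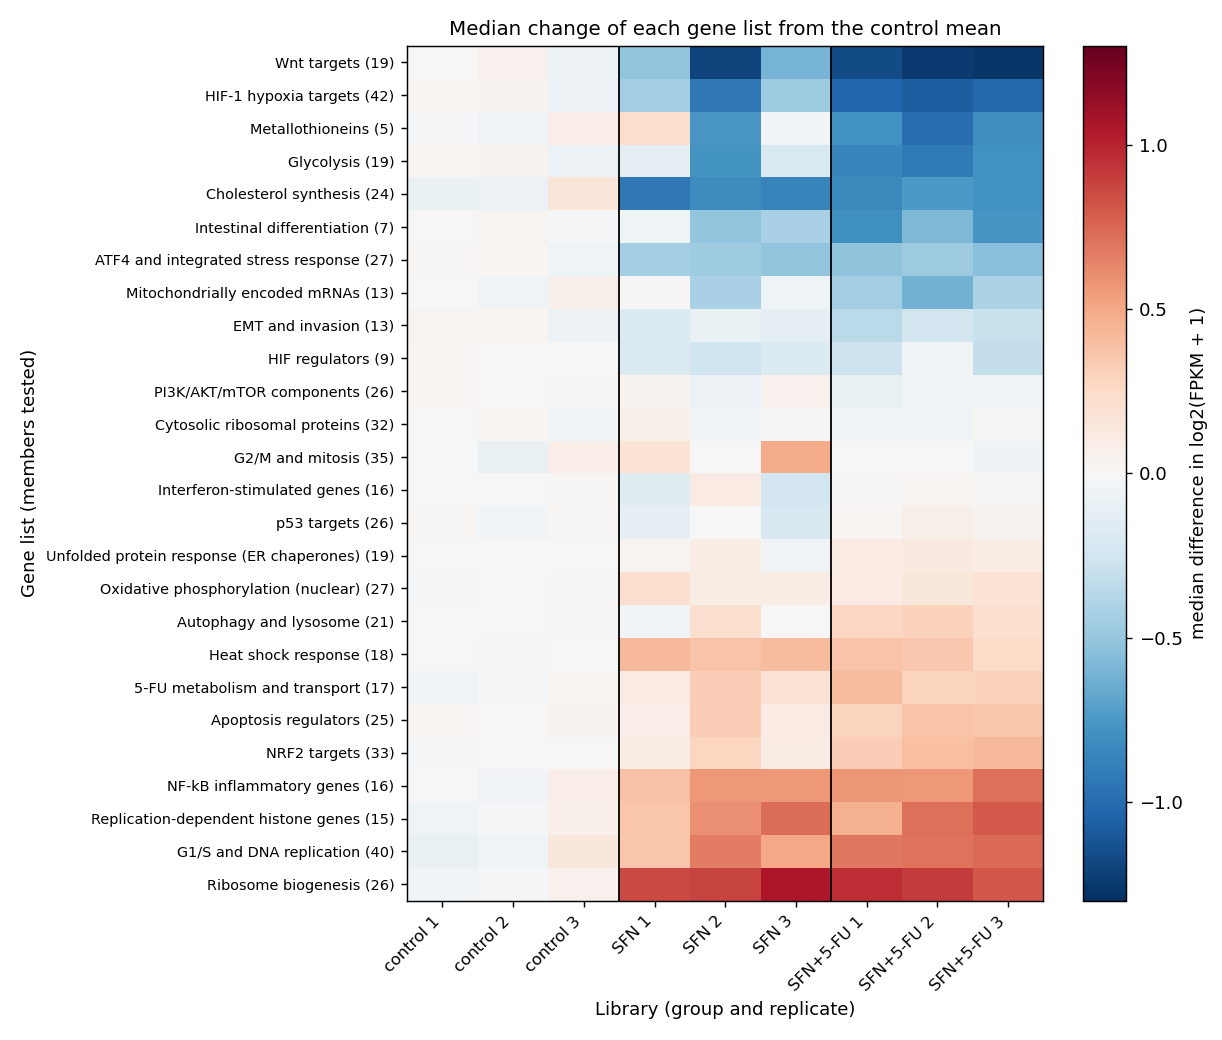
Median difference in log2(FPKM + 1) from the control mean over the tested members of each of 26 gene lists (rows, with the number of members) in each of the 9 libraries (columns, grouped by lines). Medians of HIF-1 targets lie at -0.45, -0.93 and -0.46 in SFN replicates 1, 2 and 3 and between -1.02 and -1.07 in SFN+5-FU, and those of ribosome biogenesis between 0.81 and 1.05 in all 6 treated libraries.

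The comparison of SFN+5-FU with control asks what the combination changes. HIF-1 targets were lower again: DDIT4 fell from 133 ± 18.9 to 13 ± 1.82 FPKM, CA9 from 13.2 ± 2.55 to 2.54 ± 0.722 FPKM, SLC2A1 from 487 ± 31.3 to 148 ± 4.07 FPKM and LDHA from 438 ± 15.4 to 190 ± 14.0 FPKM (mean ± SD, n = 3). Over all tested genes 66.2% were called in this comparison, and member counts near that share do not set a list apart. Of the 42 HIF-1 targets 39 fell and 1 rose (40 and 1 adjusted over the list alone), with a median log2 fold change of -1.02 (adjusted p = 2.95e-12, and adjusted p = 0.548 with an estimated correlation). VEGFA and PDK1 fell by 1.10 and 1.06 on the log2 scale. HIF1A was at 20.2 ± 2.00 FPKM, a log2 fold change of 0.14 (adjusted p = 0.201). Of 9 HIF regulators 4 fell, EGLN3 and EPAS1 by 2.82 and 1.84, and 1 rose, with the same counts adjusted over the list alone and no call for the list (median log2 fold change -0.20, and -0.13 without control replicate 2, adjusted p = 0.245). Of 19 glycolysis genes 17 fell and none rose, also adjusted over the list alone, with a median log2 fold change of -0.87 (adjusted p = 1.09e-06, and adjusted p = 0.548 with an estimated correlation).

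Mitochondrially encoded mRNAs were lower: 11 of 13 fell and none rose, also adjusted over the list alone, with a median log2 fold change of -0.49 (adjusted p = 0.00106, and adjusted p = 0.548 with an estimated correlation). MT-ATP6 fell from 5528 ± 298 to 3366 ± 412 FPKM and MT-ATP8 by 0.68 on the log2 scale. With quantile normalization the list's median was -0.08 and its call was lost (adjusted p = 0.154), as was that of MT-ATP8. That method gives equal ranks equal values in every library, so it largely removes a joint fall of the most abundant transcripts. The lost call is therefore no measure of how firm the fall is. The mitochondrial share of summed FPKM was 20.5% to 21.9% in control, 20.5%, 15.9% and 19.3% in SFN replicates 1, 2 and 3, and 13.6% to 15.6% in SFN+5-FU. With SFN alone 2 of the 13, MT-CO1 and MT-CO2, fell (none adjusted over the list alone), both calls were lost without SFN replicate 2 (adjusted p = 0.0542 and 0.0751) and without any 1 of the 3 controls (that of MT-CO1 also without SFN replicate 3, and that of MT-CO2 without SFN+5-FU replicate 1 or 3), and the list was not called (median -0.15, and -0.05 without SFN replicate 2, adjusted p = 0.172), though it was without SFN replicate 1 (median -0.25, adjusted p = 0.0468) and after the GC and length correction. The nuclear genes of oxidative phosphorylation were not called as a list with SFN+5-FU (13 of 27 higher and 5 lower, also adjusted over the list alone, median 0.15, adjusted p = 0.347, and 0.0253 with no expression filter, where it was called) or with SFN (9 higher and 1 lower, also adjusted over the list alone, median 0.15, adjusted p = 0.0835), where it was called without SFN replicate 2 (adjusted p = 0.0162, and adjusted p = 0.622 with an estimated correlation) and with no filter (adjusted p = 0.00151). NDUFS3, a complex I subunit gene, rose by 0.70 and 0.64 and NDUFA4, in SFN+5-FU, by 0.59.

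Among PI3K/AKT/mTOR components, 8 of 26 rose and 8 fell with SFN+5-FU, also adjusted over the list alone, and the list was not called (median log2 fold change -0.07, adjusted p = 0.363, and fry adjusted p = 0.0321). PIK3CB and PIK3CD, which encode catalytic subunits, fell by 0.90 and 0.80, while PIK3CA rose by 0.47. PIK3R1 rose by 0.32 (adjusted p = 0.0204), a call lost without control replicate 1, control replicate 2, SFN+5-FU replicate 1 or SFN+5-FU replicate 2 (adjusted p from 0.00119 to 0.0772 over the alternatives). AKT1 and AKT2 had log2 fold changes of -0.49 (SE 0.0578) and -0.41 (SE 0.102), with adjusted p = 0.000116 and 0.00635. After the GC and length correction these were -0.04 and -0.15, with adjusted p = 0.554 and 0.192, and over the other alternatives the adjusted p went down to 8.22e-07 and 3.43e-05. MTOR, RPS6KB1 and EIF4EBP1 had log2 fold changes of -0.11, 0.08 and -0.12, none past the threshold (adjusted p = 0.329, 0.515 and 0.103). EIF4EBP1 was past it in 6 of 23 alternatives, among them without SFN replicate 2 (adjusted p = 0.0305) and with quantile normalization (adjusted p = 0.00426), and was at 0.00 after the GC and length correction. MTOR was past it with library weights (adjusted p = 0.0396).

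NRF2 targets were not called as a list, with 19 of 33 higher and 8 lower, also adjusted over the list alone (median log2 fold change 0.38, adjusted p = 0.146), though the list was called with no expression filter (adjusted p = 0.0158). Its fry adjusted p was 0.00693. TXNRD1 rose to 79.6 ± 2.16, NQO1 to 132 ± 9.06, FTL to 4332 ± 342, SRXN1 to 66.2 ± 5.51 and GCLM to 15.4 ± 0.686 FPKM. HMOX1 rose by 0.44 on the log2 scale (adjusted p = 0.0235), a call lost without control replicate 3, SFN+5-FU replicate 1 or SFN+5-FU replicate 3 and with no expression filter (adjusted p from 0.000101 to 0.0748 over the alternatives).

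Ribosome biogenesis, cholesterol, Wnt and replication genes moved in the same directions as with SFN. In ribosome biogenesis 23 of 26 rose and none fell, also adjusted over the list alone (median log2 fold change 0.89, adjusted p = 1.87e-08, and adjusted p = 0.548 with an estimated correlation), with UTP4 and NOP16 higher by 1.28 and 1.25. MYC rose to 92.5 ± 3.87 FPKM. In G1/S and DNA replication 33 of 40 rose and none fell, also adjusted over the list alone (median 0.69, adjusted p = 5.45e-07, and adjusted p = 0.548 with an estimated correlation), with ORC6 and the cyclin E2 gene CCNE2 higher by 1.84 and 1.70. In cholesterol synthesis 19 of 24 fell and 1 rose, also adjusted over the list alone (median -0.82, adjusted p = 3.55e-07, and adjusted p = 0.548 with an estimated correlation), and INSIG1 fell by 2.63. Among Wnt targets 15 of 19 fell and 3 rose, also adjusted over the list alone (median -1.22, adjusted p = 0.000324, and adjusted p = 0.548 with an estimated correlation). APCDD1, a Wnt inhibitor, fell from 175 ± 7.77 to 22.7 ± 0.896 FPKM and CCND1 to 166 ± 10.5 FPKM. All 7 intestinal differentiation genes fell, also adjusted over the list alone (median -0.60, adjusted p = 0.00194, and adjusted p = 0.548 with an estimated correlation), VIL1 by 1.41.

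Of 27 ATF4 and integrated stress response genes 18 fell and 6 rose (19 and 6 adjusted over the list alone), with a median log2 fold change of -0.51 (adjusted p = 0.00106, and adjusted p = 0.548 with an estimated correlation). The 6 that rose included the stress-induced transcription factor gene ATF3, from 4.83 ± 0.276 to 20.3 ± 1.37 FPKM, and DDIT3, to 53 ± 7.47 FPKM. The call of DDIT3 (adjusted p = 0.0320) was lost in 8 of 23 alternatives, among them leaving out any of the 3 controls, SFN+5-FU replicate 2 or SFN+5-FU replicate 3 (adjusted p from 1.48e-05 to 0.0888). The spread behind this p value also holds the SFN libraries, SFN replicate 2 among them, so it is not the spread of the compared groups alone. The G2/M and mitosis list was not called (8 of 35 higher and 8 lower, 7 and 7 adjusted over the list alone, median -0.03, and -0.08 to 0.01 without 1 library, adjusted p = 0.524). The kinesin gene KIF20A fell by 1.07 on the log2 scale, and the mitotic kinase gene PLK1 fell by 0.94, a call lost without control replicate 2, control replicate 3, SFN+5-FU replicate 1 or SFN+5-FU replicate 2 and with no filter (highest adjusted p = 0.0626, lowest 1.08e-06). MKI67 was at 20.4 ± 1.22 FPKM (adjusted p = 0.582).

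Of 26 p53 targets 10 rose and 5 fell, also adjusted over the list alone (median log2 fold change 0.02, and 0.00 to 0.05 without 1 library, adjusted p = 0.934). BTG2 and GDF15 fell by 1.75 and 1.5, and CDKN1A was at 65.0 ± 7.76 FPKM against 67.9 ± 0.552 FPKM in control. Of 25 apoptosis regulators 15 rose and 1 fell, also adjusted over the list alone (median 0.40, adjusted p = 0.0553), and this list was called without SFN replicate 1 (adjusted p = 0.0374), without SFN+5-FU replicate 1 and with either other expression filter. In 5-FU metabolism and transport 10 of 17 rose and 4 fell, also adjusted over the list alone (median 0.33, adjusted p = 0.235), and TYMS, UPP1 and RRM2 rose by 1.22, 2.28 and 1.48. The NF-kB, histone and heat shock lists were not called (adjusted p = 0.0820, 0.0820 and 0.117). In these, 10 of 16, 10 of 15 and 10 of 18 genes rose and 1, 3 and 3 fell, also adjusted over the lists alone, with medians of 0.62, 0.65 and 0.32. The NF-kB and histone lists were called without SFN+5-FU replicate 1, with median-of-ratios scaling and with no filter, and the heat shock list with no filter. BIRC3 and the chemokine gene CCL20 rose by 1.76 and 1.25, and H4C8 and H2AC6 by 2.27 and 1.56.

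In limma, 8387 genes passed, 4847 higher and 3540 lower with SFN+5-FU, and 1331 of these changed at least 2-fold (597 higher and 734 lower). More passed without SFN replicate 2 (9461) and with only the 6 libraries compared (9592). That library is in neither of these groups but enters the shared spread, so calls lost in this comparison partly reflect it. The 8 largest increases under the same rule were IGHE, PI3, LINC00973, TXNIP, CSF3, DKK1, PSMC3IP and RPL13AP20, from 2.45 to 3.86 on the log2 scale. TXNIP, which encodes a thioredoxin-binding inhibitor of glucose uptake, rose from 18.4 ± 3.46 to 164 ± 10.6 FPKM. The 8 largest decreases were LINC02943, MYH7B, DDIT4, ENTPD8, IGFBP3, PDGFA, APCDD1 and FGD5, from -2.88 to -3.99. IGFBP3, an insulin-like growth factor binding protein gene, fell from 384 ± 24.7 to 47.4 ± 6.51 FPKM. RPL13AP20 is a pseudogene, so its reads may be those of a ribosomal protein gene.

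**Figure D3:**
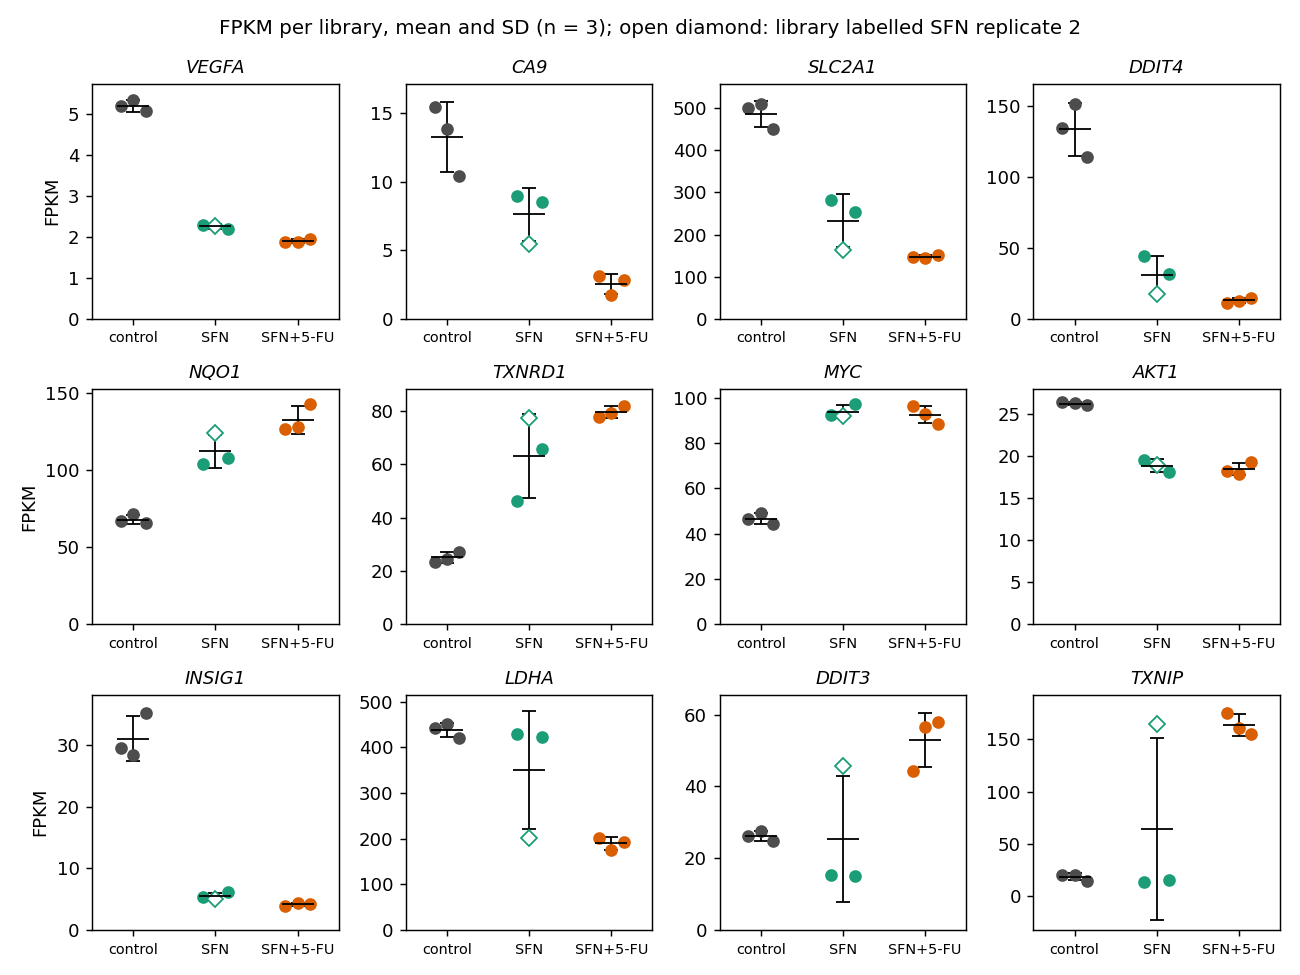
FPKM of 12 genes in each library of the 3 groups (points), with the mean and SD (bars, n = 3). SFN replicate 2 is drawn as an open diamond. VEGFA, MYC, AKT1 and INSIG1 are alike in the 3 SFN libraries, while for LDHA, DDIT3 and TXNIP SFN replicate 2 (200, 45.6 and 165 FPKM) stands apart from SFN replicates 1 and 3. The lower SD bar of TXNIP reaches below 0, where no FPKM value can lie.

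The comparison of SFN+5-FU with SFN asks what adding 5-FU changes, with the reservation that the SFN dose of the combined group is not given. With all libraries, 1 of 12662 genes passed in limma, and 3982 had an unadjusted p under 0.05. The gene has no symbol in the name table used (ENSG00000260342, named after its values were seen). It fell from 24.5 ± 5.14 FPKM with SFN to 2.95 ± 1.07 FPKM with SFN+5-FU (log2 fold change -2.71, SE 0.260, adjusted p = 0.0273) and was at 17.8 ± 5.53 FPKM in control. Its call was lost without control replicate 1, control replicate 3, SFN replicate 1, SFN replicate 3, SFN+5-FU replicate 1 or SFN+5-FU replicate 3. The call was also lost with a replicate block, with only the 6 libraries compared and with no filter. CA9 was at 7.63 ± 1.92 FPKM with SFN and 2.54 ± 0.722 FPKM with SFN+5-FU, DDIT4 at 30.9 ± 13.4 and 13 ± 1.82 FPKM, TYMS at 69.7 ± 20.8 and 97.3 ± 3.33 FPKM and DDIT3 at 25.3 ± 17.6 and 53 ± 7.47 FPKM, each with adjusted p = 0.134. HIF1A, MYC and AKT1 had log2 fold changes of 0.04, -0.02 and -0.03.

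No list held a gene past the threshold over all genes tested, and 10 of 26 lists were called by camera, none of them with an estimated correlation. Of these, fry called only HIF-1 targets and intestinal differentiation (adjusted p = 0.0468 and 0.0314). Lower with SFN+5-FU were HIF-1 targets (median log2 fold change -0.40, adjusted p = 2.95e-12), glycolysis (-0.36, 1.87e-08), mitochondrially encoded mRNAs (-0.35, 3.67e-06), Wnt targets (-0.38, 0.000615) and intestinal differentiation (-0.30, 0.00104), each with adjusted p = 0.548 with an estimated correlation. Adjusted over the list alone, 32 HIF-1 targets were lower and 2 higher, 18 glycolysis genes, 10 mitochondrial mRNAs, 10 Wnt targets and 5 intestinal genes were lower and none higher. G2/M and mitosis was lower as well (-0.24, 6.52e-06, and adjusted p = 0.567 with an estimated correlation), with no gene past the threshold adjusted over the list alone. Higher were p53 targets (0.26, 0.00346, and adjusted p = 0.548 with an estimated correlation) and NRF2 targets (0.18, 0.0108, and adjusted p = 0.574 with an estimated correlation), each with 11 higher and 2 lower adjusted over the list alone. G1/S and DNA replication (0.11, 0.00930, and adjusted p = 0.765 with an estimated correlation) and apoptosis regulators (0.18, 0.0276, and adjusted p = 0.636 with an estimated correlation) were higher with none past the threshold adjusted over the list alone. The apoptosis call was lost without SFN replicate 1 or SFN+5-FU replicate 3, the NRF2 call without SFN+5-FU replicate 3 (adjusted p = 0.0721), and the apoptosis and p53 calls with a mean FPKM filter of 5. Without SFN replicate 1 the medians of the Wnt, intestinal and apoptosis lists were -0.23, -0.18 and 0.11, without SFN replicate 2 that of apoptosis was 0.29, and without SFN replicate 3 that of G2/M and mitosis was -0.11. PI3K/AKT/mTOR components were not called (median -0.06, and -0.09 and -0.03 without SFN replicates 2 and 3, adjusted p = 0.187), nor was 5-FU metabolism and transport (median 0.21, adjusted p = 0.101), which was called without SFN replicate 1 (adjusted p = 0.0402).

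This comparison rests on SFN replicate 2. Without it 6478 genes passed, 3774 higher and 2704 lower with SFN+5-FU, of which 269 changed at least 2-fold, and SFN was then measured by 2 libraries. On that reading TXNIP rose by 3.45 on the log2 scale, the cytokine genes CSF3 and IL11 by 2.57 and 2.46, and ATF3 and DDIT3 by 1.85 and 1.73. Under the same rule, among genes with a symbol, the largest decreases were in DHRS2 (-2.34), LINC02943 (-1.88), IGFBP3 (-1.79), EGLN3 (-1.68), SLC5A3 (-1.67), C3 (-1.63), APLN (-1.57) and FGF19 (-1.51). Of the HIF-1 targets 36 fell and 3 rose, of glycolysis genes 18 fell, of G2/M genes 20 fell and 1 rose, of p53 targets 17 rose and 3 fell, and of NRF2 targets 19 rose and 2 fell. Their medians were -0.58, -0.48, -0.37, 0.35 and 0.18, and each list was called (highest adjusted p = 0.0133, and adjusted p from 0.552 to 0.566 with an estimated correlation). CA9, DDIT4, LDHA and CCND1 fell by 1.48, 1.46, 1.17 and 0.83, and TYMS and CDKN1A rose by 0.74 and 0.53.

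The responses to SFN and to SFN+5-FU against the same 3 controls were alike across genes. Pearson's r of the log2 fold changes was 0.913 and their covariance 0.289 over the 12662 genes, against 0.5 and 0.00920 in simulated groups that share controls and do not change. Without SFN replicate 2, r was 0.788 and the covariance 0.237. Both comparisons called 3142 genes higher (1331 from independent lists of these sizes) and 2584 lower (798), and none in opposite directions. The 50 simulations had a mean of 0 shared calls. Their groups hold no changed genes, so that 0 was set in advance and gives no measure for shared calls among changed genes. Without SFN replicate 2 the calls shared were 3157 higher (1649 from independent lists) and 2651 lower (1065), and 357 were in opposite directions. The simulated r and covariance allow for the shared controls and the counts from independent lists do not, so part of the excess over these counts may come from the shared controls. A split of the 3 controls between the comparisons would leave 1 library on one side.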

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

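The GC and length correction and the removal of mitochondrial transcripts were chosen after the data had been seen, and the other alternatives before. The cause of a difference was not tested unless stated.

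With a mean FPKM filter of 5, 3888 genes were called for SFN and 4903 for SFN+5-FU against control, from 6939 genes tested in place of 12662. Asking for a change of at least 2-fold left 593 and 1331. With median-of-ratios scaling 47.4% and 49.5% of the calls were higher, against 54.9% and 57.8%. These shares were 46.4% and 51.1% with no filter, and 49.2% and 51.1% with mitochondrial transcripts left out. Leaving out any 1 library gave 4845 to 7200 genes for SFN and 7287 to 9461 for SFN+5-FU, and no called gene changed sign.

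SFN+5-FU against SFN depended most on the choice made. It gave 1 gene, 0 with a replicate block, 0 with only the 6 libraries compared, and 0 without control replicate 1, control replicate 3, SFN replicate 1, SFN replicate 3, SFN+5-FU replicate 1 or SFN+5-FU replicate 3. It gave 7432 with library weights and 6478 without SFN replicate 2. With no filter the 1 gene called was higher and so is a different gene.

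Lists called were 11, 9 and 10 in the 3 comparisons, and 0, 0 and 0 with an estimated correlation. Fry called 13, 20 and 2. For SFN+5-FU against control it added NRF2 targets (adjusted p = 0.00693), PI3K/AKT/mTOR components (0.0321), apoptosis regulators (0.0126) and 5-FU metabolism (0.00493). The NF-kB (0.00321), histone (0.00193), heat shock (0.000684) and nuclear oxidative phosphorylation (0.0076) lists were added too. So were HIF regulators (0.00138) and the EMT and metallothionein lists (0.0126 each). With no filter camera called 16 lists for SFN+5-FU against control. Without any 1 library the counts were 11 to 13, 9 to 12 and 8 to 11.

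The agreement of the SFN and SFN+5-FU responses (r = 0.913) was 0.7881 without SFN replicate 2 and 0.9438 without SFN replicate 1. Of 232 gene results under up to 23 alternatives, those against control were weaker in 37 and 29 cases and stronger in 13 and 7, with 1978 and 2013 alike. For SFN+5-FU against SFN a call was gained in 72 cases, 38 with library weights and 34 without SFN replicate 2. None of the genes followed there was called with all libraries, so no call could be lost.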

Other observations

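Of the tests below, those on the position of SFN replicate 2 were chosen after its correlations had been seen, and those on HIF-1 targets and on the share of higher genes after these patterns but before the test values were seen. Epithelial and stress-related lists not described so far were not called in either comparison with control. The epithelial adhesion gene CDH1 fell from 14.2 ± 1.39 to 5.43 ± 1.11 FPKM with SFN and to 5.18 ± 0.594 FPKM with SFN+5-FU, although the EMT and invasion list had 4 of 13 genes higher and 4 lower with SFN (median log2 fold change -0.26, and -0.13 without control replicate 1, adjusted p = 0.478) and 5 and 6 with SFN+5-FU (-0.30, adjusted p = 0.350). Among 21 autophagy and lysosome genes 7 rose and 4 fell with SFN (adjusted p = 0.894) and 12 rose and 6 fell with SFN+5-FU (adjusted p = 0.596), and WIPI1, which acts in autophagosome formation, fell by 0.98 and 1.24 on the log2 scale. Among 19 ER chaperone genes 4 rose and 4 fell with SFN (adjusted p = 0.832) and 8 rose and 5 fell with SFN+5-FU (adjusted p = 0.843), and HERPUD1, an ER-associated degradation gene, fell by 1.01 and 0.80.

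Among 16 interferon-stimulated genes 5 rose and 6 fell with SFN (adjusted p = 0.426) and 6 rose and 6 fell with SFN+5-FU (adjusted p = 0.712). IRF7, an interferon regulatory factor gene, rose by 0.92 with SFN, a call lost without any 1 of the 3 controls and a value of 0.49 without SFN replicate 2, and by 1.79 with SFN+5-FU. Among 5 metallothioneins 2 rose and 2 fell with SFN (adjusted p = 0.596), MT1X by 1.06, and 2 rose and 3 fell with SFN+5-FU (adjusted p = 0.363), MT1X by 1.79, though MT1 genes are hard to tell apart by sequence. Among 32 ribosomal protein genes 5 rose and 5 fell (adjusted p = 0.826) and 9 rose and 9 fell (adjusted p = 0.612), and RPL3 fell by 0.68 (0.39 without SFN replicate 2, a call lost without control replicate 1 or 2) and by 1.32. Markers of other cell types were low. The highest marker of each kind was at 0.57 to 1.99 (fibroblast), 2.05 to 8.96 (leukocyte) and 0.75 to 2.54 FPKM (endothelial) over the 9 libraries. The median marker of each kind was at most 0.13 FPKM in any library. The fibroblast gene COL1A1 fell by 0.77 and 0.68. Of 3 tested leukocyte markers 1 rose with SFN, and 1 rose and 2 fell with SFN+5-FU. The one that rose was the macrophage marker CD68 (1.59 and 2.42), which tumour cells can express in lysosomes. LYZ fell by 0.76 with SFN+5-FU (adjusted p = 0.0246), a call lost without control replicate 2, control replicate 3, SFN+5-FU replicate 1 or SFN+5-FU replicate 3 and with no filter (adjusted p from 0.00260 to 0.0911). The endothelial marker ESAM had a log2 fold change of 0.39 with SFN (adjusted p = 0.112, called without SFN replicate 3 at 0.56, and 0.17 without SFN replicate 2) and rose by 0.83 with SFN+5-FU (adjusted p = 0.00390). For SFN+5-FU against SFN none of these lists was called with all libraries and the filter of 1 FPKM. The autophagy list (adjusted p = 0.0737) was called without SFN+5-FU replicate 1, with no filter and with a filter of 5 FPKM (lowest adjusted p = 0.00480), and the metallothioneins (adjusted p = 0.132) without SFN replicate 3 (adjusted p = 0.0431).

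SFN replicate 2 carried the SFN+5-FU profile. A swap of labels between the groups would leave an SFN+5-FU library on the SFN side, but the lowest SFN+5-FU position was 0.899 on a scale where 0 is SFN replicates 1 and 3 and 1 is SFN+5-FU. SFN replicate 2 lay at 0.911, which a single SFN+5-FU culture under that label could give. A larger response of the same genes argues less well, since of 162 genes moved by SFN in replicates 1 and 3 and moved back in SFN+5-FU, 148 (91.4%) were nearer to SFN+5-FU in replicate 2. Whether a culture reached that profile on SFN alone stays open, since its lowest correlation with an SFN+5-FU library (0.9926) would follow from either origin and favours neither.

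With all libraries, lower HIF-1 targets were not explained by the technical causes tried. The median with SFN was -0.597, and -0.55 after correction for GC content and length, which could bias FPKM. It was -0.653 with mitochondrial transcripts left out and median-ratio scaling. In 10000 lists matched for expression, 0% had a median as low, and the lowest was -0.174. These values include SFN replicate 2, whose own median was -0.926, against -0.451 and -0.462 in SFN replicates 1 and 3. Leaving out 1 library gave uncorrected medians of the HIF-1 targets from -0.689 to -0.435. A reduced HIF response, for instance through less HIF-1α protein, could lower these genes without a fall in HIF1A mRNA, which a protein blot at 1% oxygen would test.

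More genes were higher than lower with SFN+5-FU, with a median log2 fold change of 0.0967 over all genes. Leaving mitochondrially encoded transcripts out gave 0.0259 and 51.1% of calls higher, so the smaller mitochondrial share could account for much of that shift in FPKM. Bias from GC content and length stays open, since the correction for them keeps each library's mean level and so leaves the share of higher calls (57.6%, against 57.8%) undecided.

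Regrouping the 6 libraries of each comparison gives 10 splits, the real one included. The number with a count at least as large as the real one was 1, 1 and 3 for genes and 5, 8 and 3 for lists. With 10 splits no share can fall under 0.05. Other splits called up to 13, 12 and 10 lists, against 11, 9 and 10 for the real groups. The number of lists called by camera therefore does not separate the real grouping from mixed ones. For genes, other splits of the comparisons with control called 0. Mixing treated and control libraries puts their difference into the spread within groups, so a low count was built in.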
